A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

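The data were the signals of 12 one-colour Affymetrix yeast arrays, 1 per culture, from 4 groups (strains M25 and EC1118, each in SJ and FSJ) with 3 biological replicates per group, per the labels. Cultures were started from a 24 h preculture at 1000000 cells/ml, grown at 28°C and harvested at 60 h, per the labels' protocols. The deposited values are intensity on a linear scale, 1 per probe set and array, made with MAS5 per the submitters' processing notes. Its version and scaling target are not given in the sources used here. The mean of the deposited intensities between the 2nd and 98th percentiles was 300.2 to 300.3 on every array, so the deposited scale was kept.

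Of 9335 probe sets, 60 control probe sets were left out. Of the 9275 others, 6504 had 1 gene symbol, 328 had several and 2443 had none in the probe table used here. The background of an array was the 25th percentile of these 9275 signals, and a probe set was kept if it exceeded the background on at least 3 of the 12 arrays. This left 7349 probe sets, of which 1245 carry a suffix that marks family or shared probes. Where a gene had several probe sets, which held for 257 genes, the probe set with the highest mean stood for it, and no gene was named from a probe set with several symbols. This gave 5360 genes. Gene types and neighbours came from the table of assembly R64, and no coordinates are given.

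Signals under 1 were set to 1 before log2. Group means were fitted on all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and p-values were adjusted by Benjamini-Hochberg over the 7349 probe sets, with a threshold of 0.05. The contrasts were FSJ over SJ averaged over the strains, FSJ over SJ within each strain, their difference (EC1118 minus M25, the interaction) and EC1118 over M25 within each medium. Every adjusted p of a gene comes from limma. Fold changes are on the log2 scale of these signals and SE is that of the fit. Where a group was under the background on all 3 arrays, the fold was computed against the background and is given as at least that size, and no fold is given where both groups were or where it was under 1. Replicates of a group had log2 correlations of 0.919 to 0.986 and at most 1.29% identical values.

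The 36 gene lists (9 of lipid metabolism and 27 others) were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists, with an estimated correlation as an alternative. The contrasts, lists, filters, thresholds, alternatives and rule for named genes were chosen before the data were examined, apart from the choices said to have been made later. For the averaged effect the rule named the 12 largest rises and 12 largest falls among called genes with the same sign and separate arrays in both strains, up to 4 members with the smallest p of each list, and OLE1, ERG1, ERG3, ERG11, HMG1, HMG2, UPC2, AUS1, DAN1, TIR1, INO1, HSP12, HEM13 and ACC1. It named 5 genes per direction by fitted size within each strain, 6 per direction by smallest p in the interaction, and 8 per direction by size among genes called in both media between the strains.

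The fits were tested on simulated data with 200 altered probe sets among 7349. Of changes of 1 on the log2 scale, 89.6% were recovered for the averaged effect, 70.1% in M25, 68.7% in EC1118 and 35.8% in the interaction, and of changes of 2 on that scale 86.4% were recovered in the interaction. Unaltered probe sets made up 4.27% of the calls for the averaged effect and 8.79% in the interaction. The simulated noise was independent between probe sets and arrays, with no scaling shift between groups and no outlying array. The shares in the real data can therefore differ from these. Alternatives were quantile normalization, centring of arrays on their medians, log2(signal + 16), signals raised to the background, no filter, a stricter filter, the replicate number as a block, no intensity trend, the mean of a gene's probe sets, only the groups compared, and leaving out each array in turn.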

Results

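Gene expression was measured in a pair of wine strains of Saccharomyces cerevisiae, EC1118, a commercial strain, and M25, a wild-type strain from a university culture collection. Cells were harvested after 60 h in a synthetic grape juice without lipids (SJ, 200 g/l glucose, pH 3.3) or in the same juice with 15 mg/l ergosterol and 15 mg/l oleic acid (FSJ). Each of the 4 combinations of strain and medium had 3 biological replicates, 12 one-colour arrays in all. The trimmed mean signal was 300.2 to 300.3 on every array. The background, the 25th percentile of the yeast probe sets on an array, was 16.6 to 21.7. The median log2 signal of the probe sets kept was 7.09 ± 0.02 in M25 in SJ, 6.90 ± 0.01 in M25 in FSJ, 7.08 ± 0.02 in EC1118 in SJ and 7.15 ± 0.02 in EC1118 in FSJ (SD, n = 3). EC1118 in FSJ was the least uniform group, with a lowest correlation of 0.919, between replicates 2 and 3. On the second principal component (13.3% of the variance) replicate 2 lay at -49.2, replicate 1 at -2.41 and replicate 3 at 11.6, above EC1118 in SJ replicates 2 (9.36) and 3 (9.83). In replicate 2 the signal for the spiked bacterial transcript BioDn was 432, against 1000 to 1446 on the other arrays. The ratio of 3' to 5' signal of ACT1 had group means of 1.44 to 1.52. An exact two-sided permutation test between media gave p = 0.8 in each strain, but with 3 arrays against 3 the smallest possible p is 0.1, so it cannot show that the media were alike. The corresponding ratio for the TATA-binding protein transcript had group means of 2.07 to 3.55 (exact two-sided permutation p = 0.2 in M25 and 0.5 in EC1118). The highest, 3.55 ± 1.82 (SD, n = 3) in M25 in FSJ, held replicate 2 at 5.64 beside 2.61 and 2.39, and that array had the lowest ACT1 ratio of all, 1.21. The number of arrays limits the precision of every value below.

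The main comparison asked which transcripts responded to lipids on average over the strain backgrounds, as the mean of the M25 and EC1118 effects of FSJ over SJ, and a call here does not need a call in each strain. Growth, fermentation and viability were not analysed here, so whether the SJ and FSJ cultures were at the same growth stage at 60 h is not known. Every value of FSJ over SJ holds the medium and any difference in stage together. The steepest falls with lipids were in SUE1, whose product takes part in the turnover of cytochrome c, and in the seripauperin genes of the PAU family. SUE1 fell from 219 ± 72.7 to 25.5 ± 4.89 in M25 and from 218 ± 149 to 27.8 ± 10.7 in EC1118 (signal, SD, n = 3; 7.67-fold on average, SE 0.31 on the log2 scale, limma adjusted p = 0.000123). The SUE1 signals in FSJ lay near the background of 16.6 to 21.7, so the size and rank of its fall are uncertain. Over its alternatives the fitted value was -3.17 to -2.36 on the log2 scale. PAU17 fell from 4192 ± 176 to 520 ± 62.6 in M25 and from 5456 ± 300 to 1059 ± 178 in EC1118 (6.48-fold, adjusted p = 5.97e-09). SUL1, the high-affinity sulfate permease, had the largest fitted average rise (4.16-fold, SE 0.12 on the log2 scale, adjusted p = 1.25e-06). Over its alternatives the rise was 1.78 to 2.12 on the log2 scale. Its signal went from 53.6 ± 3.47 to 675 ± 68.2 in M25. In EC1118 its signals were 17.1 ± 2.40 and 23.7 ± 4.42, over the background on 1 of the 3 SJ arrays and 2 of the 3 FSJ arrays. The EC1118 part of this average is therefore uncertain. DAL5, the allantoate permease, rose 2.69-fold (SE 0.13 on the log2 scale, adjusted p = 2.79e-05). Its other probe sets went both ways, with -0.47 (adjusted p = 0.024) and 1.52 (adjusted p = 0.000282) on the log2 scale.

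The other large falls were in PAU23 (5.42-fold), PAU15 (4.91-fold), YPR145C-A (4.75-fold), JID1 (4.19-fold), PAU16 (4.05-fold), HES1 (3.98-fold), PAU3 (3.90-fold) and FMP48 (3.78-fold). HPA2, a histone acetyltransferase, also fell and was under the background on all 3 arrays of M25 in FSJ, where the fall was at least 2.27-fold. BAG7, a GTPase-activating protein, was under the background on all FSJ arrays, which allows falls of at least 1.14-fold in M25 and at least 1.25-fold in EC1118. Its call was lost with signals raised to the background (adjusted p = 0.281, against 0.000161 to 0.281 over its alternatives). Rises followed in the G1 cyclin genes PCL1 (2.96-fold) and CLN1 (2.22-fold), YOX1 (2.33-fold), the glycerophosphoinositol permease GIT1 (2.28-fold), the sulfur regulator MET32 (2.16-fold) and the urea transporter DUR3 (2.12-fold). The S-phase cyclin gene CLB6 was called higher (adjusted p = 0.011), with 17.5 ± 4.51 and 48.5 ± 7.02 in M25, where 1 of the 3 SJ arrays was over the background and no fold is given. In EC1118 it was under the background on all 3 SJ arrays and its bound was under 1, so no fold is given. The tRNA genes YNCJ0011W (2.18-fold) and SUF1 rose too, SUF1 from under the background (at least 1.38-fold in M25 and at least 1.04-fold in EC1118). The SUF1 call was lost with signals raised to the background (adjusted p = 0.164, against 0.0105 to 0.164 over its alternatives) and without M25 in FSJ replicate 1 (0.0501) or 2 (0.0525). In EC1118, PCL1 and YNCJ0011W were over the background on 1 of the 3 SJ arrays, SUF1 on 1 and HPA2 on 2 of the 3 FSJ arrays, and BAG7 on 2 of the 3 SJ arrays in each strain. The averages printed for PCL1 and YNCJ0011W are thus fitted values with an uncertain EC1118 part. Over their alternatives they ranged from 1.24 to 1.78 and from 0.78 to 1.25 on the log2 scale. FIT2, a siderophore-binding mannoprotein, was called higher (adjusted p = 0.0172), with 67.2 ± 27.3 and 163 ± 10.3 in EC1118. In M25 it was under the background in both media, so no fold is given.

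**Figure D1:**
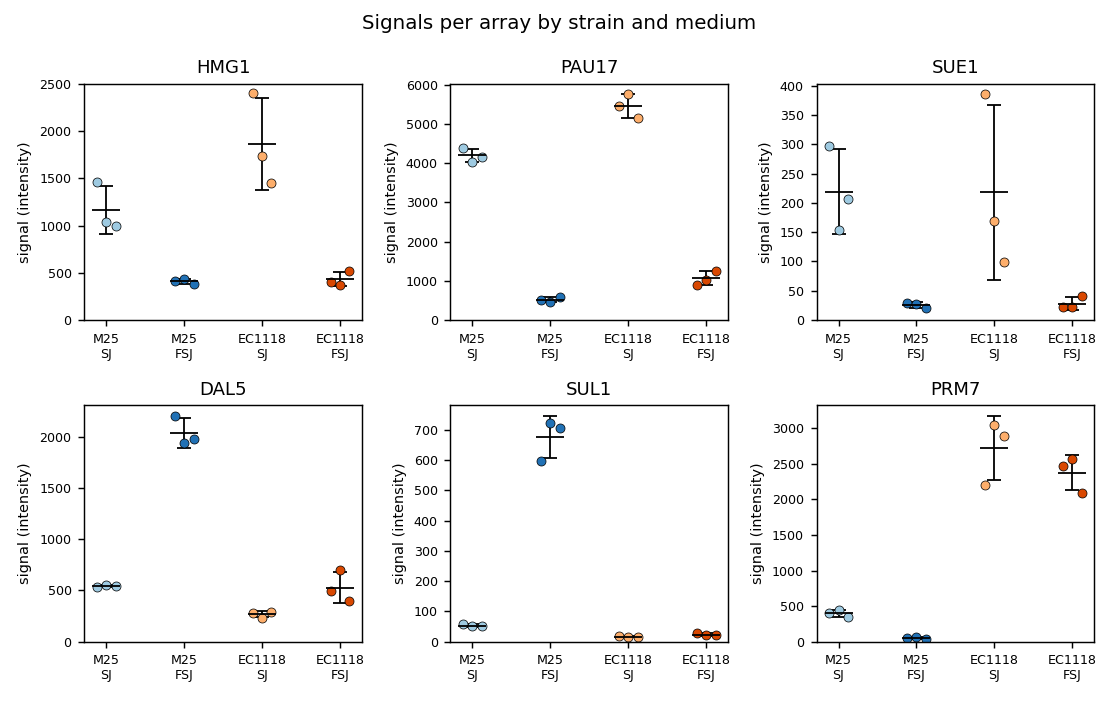
Signal (intensity, linear axis from 0) of 6 genes on each of the 12 arrays, by strain and medium; points are arrays, bars the group mean and its SD (n = 3). HMG1, PAU17 and SUE1 lie lower in FSJ than in SJ in both strains, DAL5 lies higher in both, and SUL1 and PRM7 differ between media mainly in M25.

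The lists for ergosterol biosynthesis and for sterol uptake, esters and regulators were called lower with lipids. Of 24 measured ergosterol biosynthesis genes, 18 fell and none rose (20 fell adjusted over the list alone), with a median log2 fold change of -0.40 and a limma camera adjusted p of 3.44e-14. It was adjusted p = 0.137 with an estimated correlation. HMG1, an HMG-CoA reductase early in the pathway, fell from 1166 ± 257 to 411 ± 24.7 in M25 and from 1862 ± 487 to 432 ± 73.3 in EC1118 (log2 fold change -1.79, SE 0.14, adjusted p = 1.35e-05). ERG8 fell by 0.97, ERG24 by 0.79, ERG3 by 0.50, ERG11 by 0.40 and ERG1 by 0.35 on the log2 scale. HMG2, the other reductase gene, did not pass (-0.12, adjusted p = 0.445). Of 22 genes for sterol uptake, esters and their regulators, 7 fell and 1 rose (10 and 2 adjusted over the list alone). Camera gave this list adjusted p = 0.00308, and adjusted p = 0.186 with an estimated correlation. Within strains it was called in EC1118 (3 of 22 fell, or 9 fell and 2 rose adjusted over the list alone; 0.000144, and adjusted p = 0.14 with an estimated correlation). It was not called in M25 (0.0741, but 0.0231 with quantile normalization) or in the interaction (0.808). In M25 6 of 22 fell (6 fell and 1 rose adjusted over the list alone). The list median was -0.30 in M25 and -0.14 in EC1118 on the log2 scale. Camera sets a list against the other genes, and the median of all genes was -0.11 in M25 and 0.079 in EC1118. The falls included the sterol-responsive transcription factor UPC2 (by 1.05), the repressor MOT3 (by 1.56), the steryl ester hydrolase YEH1 (by 0.99) and the sterol importer AUS1 (by 0.91). The AUS1 call was lost when its probe sets were averaged (adjusted p = 0.102, against 0.000505 to 0.102 over its alternatives). The gene that rose was PRY2 (0.69 on the log2 scale), named after its value was seen.

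All 10 measured PAU genes of the 24 on the list fell (10 adjusted over the list alone), with a median log2 fold change of -1.85 and a camera adjusted p of 2.44e-21 (adjusted p = 0.0826 with an estimated correlation). Their probe sets are family probe sets that can read near-identical copies, so the share of each copy is uncertain. Among the 6 DAN/TIR mannoprotein genes, which are also known from anaerobic growth, only DAN4 fell (by 0.59 on the log2 scale, adjusted p = 0.0107; 1 adjusted over the list alone). The list was not called (adjusted p = 0.845), and its median of 0.0052 and its test, downward, differ in sign. With quantile normalization the median was -0.089. DAN1 gave signals of 5467 ± 225 and 5701 ± 392 in M25 and 5712 ± 283 and 4997 ± 163 in EC1118 in SJ and FSJ (log2 fold change -0.067, adjusted p = 0.459), and TIR1 gave 0.17 (adjusted p = 0.32). None of OLE1, the fatty acid desaturase (0.013, adjusted p = 0.93), ACC1, acetyl-CoA carboxylase (-0.011, adjusted p = 0.936), and INO1, inositol phosphate synthase (-0.0087, adjusted p = 0.948), passed the test.

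**Figure D2:**
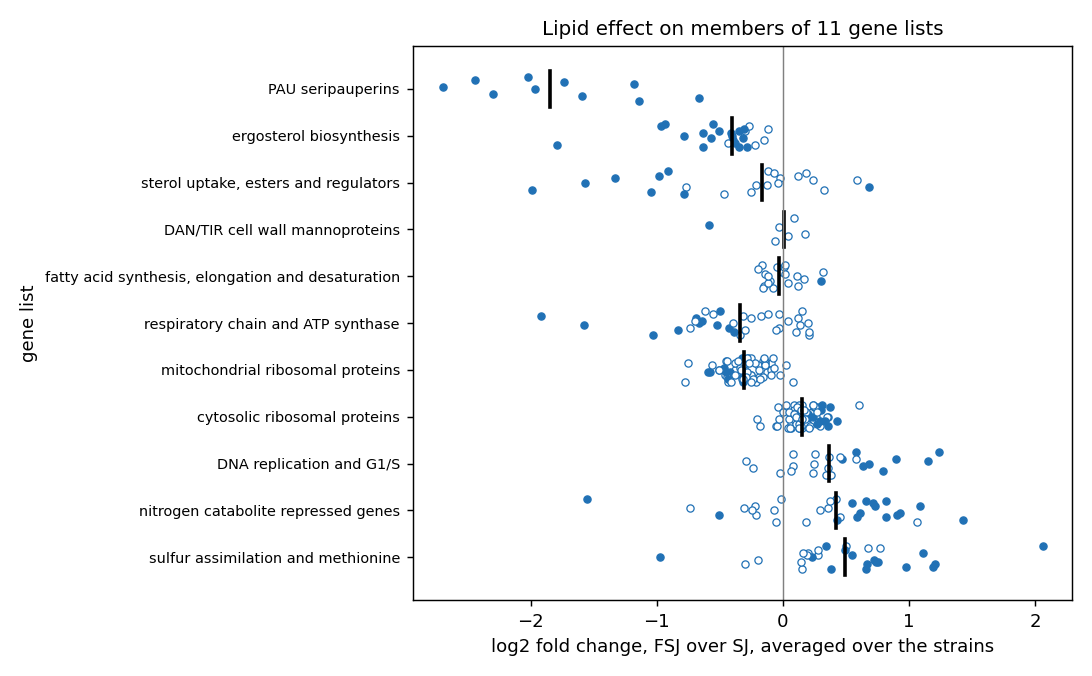
Average log2 fold change of FSJ over SJ (horizontal axis) of every measured member of 11 gene lists; filled points passed adjusted p under 0.05, open points did not, and vertical bars are list medians. All 10 measured PAU genes and 18 of 24 ergosterol biosynthesis genes fell, and 15 of 28 sulfur assimilation genes rose.

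The beta-oxidation list was called lower, with a median of -0.33 on the log2 scale, or -0.32 with groups under the background set to it (2 of 23 fell, or 6 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00608, and adjusted p = 0.334 with an estimated correlation). It was called in EC1118 (0.00197, and adjusted p = 0.248 with an estimated correlation; 0.0541 without EC1118 in FSJ replicate 2) and neither in M25 (0.166) nor in the interaction (0.326). In M25 3 of 23 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.28. The EC1118 median was -0.24, or -0.18 with groups under the background set to it. Of 26 sphingolipid genes, 7 fell, among them the sphingoid base phosphatase YSR3 (by 1.25) and IPT1 (by 0.89), and SUR2 rose (0.36). That list was not called (adjusted p = 0.0795; 8 fell and 3 rose adjusted over the list alone). Fatty acid synthesis was not called (1 of 20 rose and none adjusted over the list alone; adjusted p = 0.933). The phospholipid synthesis (2 of 25 rose, OPI1 by 0.46 and CPT1 by 0.30, and 2 adjusted over the list alone; adjusted p = 0.78; median -0.015 with an upward test) and triacylglycerol lists (1 of 16 fell, 6 adjusted over the list alone; adjusted p = 0.109) were not called either.

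The respiratory chain, mitochondrial ribosomal protein, oxidative stress and stationary phase lists were called lower with lipids. Of 33 genes of the respiratory chain and ATP synthase, 11 fell and none rose (15 adjusted over the list alone), with a median of -0.34 on the log2 scale (camera adjusted p = 4.26e-05; adjusted p = 0.313 with an estimated correlation). Cytochrome c, CYC1, fell by 1.57 (SE 0.15) and cytochrome c1, CYT1, by 1.03 (SE 0.14). Of 67 mitochondrial ribosomal protein genes, 10 fell (17 adjusted over the list alone), among them MRPS8 by 0.58 and MRPL20 by 0.42. The list median was -0.31 (camera adjusted p = 3.82e-10; adjusted p = 0.137 with an estimated correlation). Of 29 oxidative stress genes 6 fell (8 adjusted over the list alone), including the superoxide dismutase SOD2 (by 0.85) and the peroxiredoxin TSA2 (by 0.77). Their camera adjusted p was 0.00308 (adjusted p = 0.358 with an estimated correlation). The stationary phase list was called lower (7 of 29 fell and 2 rose, or 8 and 2 adjusted over the list alone; adjusted p = 0.00532, and adjusted p = 0.517 with an estimated correlation). The oxidative stress and stationary phase calls were met in EC1118 (7.09e-05 and 0.000633; adjusted p = 0.225 and 0.425 with an estimated correlation) and not in M25 (0.218 and 0.205). Camera sets a list against the other genes. The median of all genes was -0.11 in M25 and 0.079 in EC1118 on the log2 scale. The medians of these lists were -0.18 and -0.34 in M25, and -0.16 and -0.12 in EC1118. As deposited, neither median was lower in EC1118 than in M25. In M25 4 oxidative stress genes fell (7 adjusted over the list alone). In EC1118 1 oxidative stress gene fell (2 adjusted over the list alone) and no stationary phase gene passed, and the latter call was lost without EC1118 in FSJ replicate 2 (0.0541). The interaction was called for neither list (0.0902 and 0.207). Respiratory, stationary phase, replication and ribosome genes are known to vary with growth stage, which was not analysed here. The stationary phase member SIP18 fell at least 5.91-fold in M25, and HSP12 did not pass (-0.38 on average, adjusted p = 0.616).

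Some lists were called lower on narrow margins, none of them called in M25 on the deposited scale. The glycerol, acetate and ester list (4 of 26 fell, or 6 fell and 1 rose adjusted over the list alone, with GPP2 falling by 0.67 and GUT2 by 1.43) had an adjusted p of 0.0232 (adjusted p = 0.313 with an estimated correlation), and 0.0517 without EC1118 in SJ replicate 1. It was called in neither M25 (0.11, but 0.027 with quantile normalization) nor EC1118 (0.0586). The trehalose and glycogen list (2 of 20 fell, 2 adjusted over the list alone) had 0.0297 (adjusted p = 0.668 with an estimated correlation). The trehalose call was lost without M25 in SJ replicate 3 (0.053), M25 in FSJ replicate 1 (0.118) or 2 (0.0638), EC1118 in SJ replicate 1 (0.139), or EC1118 in FSJ replicate 1 (0.105) or 2 (0.061). The heme list (2 of 9 fell, HMX1 by 1.46 and HEM2 by 0.73, and 2 adjusted over the list alone) had 0.046 (adjusted p = 0.186 with an estimated correlation). The heme call was lost without M25 in SJ replicate 1 (0.0753) or 3 (0.053), M25 in FSJ replicate 2 (0.0701), EC1118 in SJ replicate 2 (0.0538) or 3 (0.0655), or EC1118 in FSJ replicate 2 (0.0883) or 3 (0.139). The trehalose and heme lists were called in EC1118 (0.000806 and 0.00335; adjusted p = 0.442 and 0.121 with an estimated correlation), where 0 of 20 and 1 of 9 members fell (0 and 2 adjusted over the list alone). Neither was called in M25 (0.621 and 0.457) or in the interaction (0.0723 and 0.18).

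The sulfur, nitrogen, amino acid and thiamine lists were called higher with lipids. Of 28 sulfur assimilation genes, 15 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.49 on the log2 scale (camera adjusted p = 6.5e-10; adjusted p = 0.186 with an estimated correlation). Examples were SUL1, the cysteine transporter YCT1 (1.21, SE 0.14) and MET2 (0.98, SE 0.15). The member that fell was the methionine permease MUP1 (by 0.97), named after its value was seen. Of 30 nitrogen catabolite repressed genes, 13 rose and 2 fell (17 and 5 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 1.67e-05; adjusted p = 0.158 with an estimated correlation). The general amino acid permease GAP1 rose by 0.90, DAL3 by 0.81 and the ammonium permease MEP2 by 0.55 on the log2 scale. The proline permease PUT4 fell by 1.56 and the arginase CAR1 by 0.50, both named after their values were seen. Of 63 amino acid biosynthesis genes, 11 rose, including HIS3 (0.47) and ARO8 (0.40), and none fell (17 rose adjusted over the list alone). Camera gave adjusted p = 2.05e-08 there, and adjusted p = 0.186 with an estimated correlation. In the thiamine and pyridoxine list 5 of 14 rose (6 adjusted over the list alone), among them SNZ1 (0.47). That list had a camera adjusted p of 0.00308 (adjusted p = 0.426 with an estimated correlation). Within strains, the sulfur, amino acid and thiamine lists were called in M25 (3.11e-17, 2.37e-14 and 0.000751; adjusted p = 0.112, 0.112 and 0.456 with an estimated correlation) and not in EC1118 (0.246, 0.357 and 0.155). No member of these lists passed in EC1118 (adjusted over the list alone 1 sulfur and 2 thiamine genes rose and 1 thiamine gene fell). The interaction was called for the sulfur (4.62e-17) and amino acid lists (7.63e-12; adjusted p = 0.182 and 0.215 with an estimated correlation) and not for thiamine (0.0614), which with quantile normalization was called in EC1118 too (0.0295). The nitrogen list was called in M25 (6.29e-06) and in EC1118 (0.00247), with adjusted p = 0.112 and 0.225 with an estimated correlation.

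Of 24 genes of DNA replication and the G1/S transition, 8 rose and none fell (9 adjusted over the list alone), with a median of 0.36 on the log2 scale (camera adjusted p = 5.57e-07; adjusted p = 0.186 with an estimated correlation). They included the G1 cyclin CLN1 (1.15), the replication licensing factor CDC6 (0.90) and MCM7 (0.47). Of 81 cytosolic ribosomal protein genes, 16 rose (24 adjusted over the list alone) by small amounts, such as RPL16A by 0.35 (SE 0.08). The median of the list was 0.15 (camera adjusted p = 2.75e-09; adjusted p = 0.186 with an estimated correlation), and with quantile normalization 0.078 (0.00272). The list was called in M25 (2.41e-18; adjusted p = 0.112 with an estimated correlation) and not in EC1118 (0 of 81 passed, also adjusted over the list alone; median 0.037; 0.787). The interaction was called as deposited (4.62e-17; adjusted p = 0.158 with an estimated correlation) and not with quantile normalization (0.184). Of 51 ribosome biogenesis genes 7 rose (10 adjusted over the list alone), including RPF2 (0.86) and RRP5 (0.53). Camera gave them an adjusted p of 1.34e-07 (adjusted p = 0.426 with an estimated correlation).

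The remaining lists were not called for the averaged lipid effect. Of 17 hypoxic genes 3 fell (4 fell and 1 rose adjusted over the list alone), among them the repressor ROX1 (by 1.67) and CYC7 (by 1.37). The list had adjusted p = 0.421, and HEM13 gave 0.071 (adjusted p = 0.91). In hexose transport HXT2 fell by 1.70 and HXT4 by 0.67 (2 of 14, or 3 adjusted over the list alone; list adjusted p = 0.302). In the iron regulon 3 of 28 fell, including the copper transporter CCC2 (2.82-fold), and 2 rose (5 and 3 adjusted over the list alone; list adjusted p = 0.794). The list p-values were 0.104 for phosphate and zinc (3 of 23 rose, with PHO84 at 0.57, and 1 fell, the same counts adjusted over the list alone) and 0.155 for heat shock proteins (1 of 29, HSP30, rose by 0.69, and 1 adjusted over the list alone). They stood at 0.327 for cell wall proteins (3 of 34 rose and 1 fell, or 4 and 1 adjusted over the list alone) and 0.893 for drug efflux (1 of 26, ATR1, rose by 0.70 and PDR16 fell by 0.88; 4 rose and 4 fell adjusted over the list alone). They were 0.214 for mating genes (1 of 15 rose, or 1 rose and 1 fell adjusted over the list alone) and 0.893 for the TCA cycle (2 of 23 rose, and 2 adjusted over the list alone). Genes variable between strains had 0.845 (2 of 15 fell, including SUC2 by 0.62, and 2 adjusted over the list alone; median -0.0043 with an upward test). No member passed, over all genes or adjusted over the list alone, in glycolysis (24 measured, adjusted p = 0.78), flocculins (8, adjusted p = 0.78) or meiosis (15, adjusted p = 0.793; median 0.0031 with a downward test). With quantile normalization the medians of the glycolysis (0.035 to -0.043), flocculin (-0.028 to 0.019) and strain-variable lists (-0.0043 to 0.061) turned in sign. With groups under the background set to it, the medians were -0.0046 for flocculins and 0.012 for meiosis, and apart from beta-oxidation those printed for the other lists of this contrast were the same to 2 decimals.

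Over 5360 genes, limma called 560 for the averaged lipid effect, 248 higher and 312 lower with lipids, and 83 of them changed at least 2-fold, 17 up and 66 down. In 334 of the called genes (142 up and 192 down) the 3 FSJ arrays lay wholly on one side of the 3 SJ arrays in each strain. Such separation, the same way in both strains, held for 7.67% of all genes against 0.5% by chance. The direction split depended on the scaling: with arrays centred on their medians 661 genes were called, 411 higher and 250 lower. Without M25 in SJ replicate 3 the count was 353.

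Within M25, lipids changed 512 genes, 161 higher and 351 lower, and 146 of these at least 2-fold. SUL1 rose 12.6-fold (SE 0.17 on the log2 scale, adjusted p = 2.49e-07), YCT1 4.11-fold, DAL5 3.74-fold and the minor pyruvate decarboxylase gene PDC6 3.13-fold, from 118 ± 1.96 to 381 ± 106 (n = 3). FIT2 was also called (adjusted p = 0.0356), with both groups under the background and no fold given. Its call was lost without M25 in SJ replicate 2 (0.126) or 3 (0.128), M25 in FSJ replicate 1 (0.101), 2 (0.0934) or 3 (0.0537), or EC1118 in FSJ replicate 1 (0.0502). Falls included SUE1 (8.38-fold, to near the background), PAU17 (8.09-fold) and YPR145C-A (7.28-fold). SIP18 (at least 5.91-fold) and BSC1 (at least 2.97-fold) fell to under the background, so their size has no rank. SUL1 and YCT1 were the only ones of these genes to pass the interaction test, with adjusted p = 0.148 for PDC6, 0.15 for BSC1 and 0.253 for SIP18. The lists were tested within each strain after the data were examined. In M25 limma camera called 13 lists, 9 higher and 4 lower, none with an estimated correlation (lowest adjusted p = 0.112 with an estimated correlation). They included the cytosolic ribosomal proteins (14 of 81 rose, 38 adjusted over the list alone; adjusted p = 2.41e-18), the sulfur genes (16 of 28 rose and 1 fell, or 20 and 1 adjusted over the list alone; adjusted p = 3.11e-17) and the PAU genes (10 of 10 fell, and 10 adjusted over the list alone; adjusted p = 5.18e-17). Each had adjusted p = 0.112 with an estimated correlation, as did amino acid biosynthesis (12 of 63 rose, or 25 rose and 1 fell adjusted over the list alone; adjusted p = 2.37e-14). With quantile normalization the ribosomal protein median went from 0.27 to 0.11 and its adjusted p was 0.00161, against 1.99e-12 for the sulfur and 2.25e-21 for the PAU genes. The ergosterol list was lower (11 of 24 fell, 17 adjusted over the list alone; adjusted p = 2.07e-06, and adjusted p = 0.258 with an estimated correlation). So were the mitochondrial ribosomal proteins (12 of 67 fell, 18 adjusted over the list alone; adjusted p = 7.69e-07, and adjusted p = 0.186 with an estimated correlation). The glycolysis call (1 of 24 rose, and 1 adjusted over the list alone; adjusted p = 0.00309, upward; adjusted p = 0.255 with an estimated correlation) turned downward and was lost under quantile normalization (0.753). The cell wall list was called higher (3 of 34 rose and 1 fell, or 4 and 1 adjusted over the list alone; 0.0265, and adjusted p = 0.287 with an estimated correlation). That call was lost without M25 in FSJ replicate 1 (0.0676) and with quantile normalization (0.76). The respiratory chain list was called lower (6 of 33 fell and 1 rose, or 10 and 1 adjusted over the list alone; 0.0211, and adjusted p = 0.65 with an estimated correlation). That call was lost without M25 in SJ replicate 2 (0.0626) or M25 in FSJ replicate 2 (0.0596).

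The median of all genes in M25 was -0.11 on the log2 scale as deposited, -0.0099 with quantile normalization and 0.075 with arrays centred on their medians. The fold changes of M25 are to be read relative to it. The split of 161 higher and 351 lower became 149 and 193 with quantile normalization and 465 and 191 with centring, so the majority direction in M25 turned with the scaling. Leaving out M25 in SJ replicate 1, 2 or 3, or M25 in FSJ replicate 2, reduced the count of 512 to 250, 256, 242 and 323.

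Within EC1118, lipids changed 113 genes, 42 higher and 71 lower, 46 of them at least 2-fold. MMO1 rose from 456 ± 98.4 to 1303 ± 227 (2.87-fold, SE 0.19 on the log2 scale, adjusted p = 0.00139, n = 3), and rises followed in the tRNA gene YNCJ0011W (16.1 ± 5.07 and 43.1 ± 6.15, over the background on 1 of 3 SJ arrays, with no fold given), HLR1 (2.66-fold), CDC6 (2.54-fold) and GIT1 (2.41-fold). Falls included SUE1 (7.01-fold, to near the background), PAU17 (-2.38 on the log2 scale), PAU23 (5.19-fold) and CYB2, the lactate cytochrome c oxidoreductase (5.12-fold). BAG7 was under the background in FSJ, with a bound of at least 1.25-fold. The CYB2 call was lost without EC1118 in FSJ replicate 1 (0.0515) or 2 (0.0629). None of these genes passed the interaction test, with adjusted p = 0.125 for MMO1, 0.231 for HLR1 and 0.51 for CYB2. Camera called 18 lists, 3 higher and 15 lower, of which the PAU list (10 of 10 fell, and 10 adjusted over the list alone; adjusted p = 4.74e-28) alone was also called with an estimated correlation (adjusted p = 0.0356 with an estimated correlation). The ergosterol list was next (12 of 24 fell, 18 adjusted over the list alone; adjusted p = 7.24e-21, and adjusted p = 0.0636 with an estimated correlation). Ribosome biogenesis led the lists that were higher (0 of 51 members called, also adjusted over the list alone; median 0.37; adjusted p = 5.34e-08, and adjusted p = 0.423 with an estimated correlation). The calls of the glycolysis, hypoxic, DAN/TIR, sphingolipid and hexose transport lists were lost under quantile normalization (0.0549 to 0.0657). Of their members, 1 sphingolipid gene passed over all genes. Adjusted over the list alone, 2 sphingolipid, 3 hypoxic, 1 DAN/TIR and 1 hexose transport gene fell and 2 hypoxic genes rose. These 5 lists had adjusted p = 0.225 to 0.442 with an estimated correlation. Without EC1118 in SJ replicate 1 the DAN/TIR (0.0814), sphingolipid (0.0615) and hexose transport (0.179) calls were lost, and without EC1118 in FSJ replicate 1 the DAN/TIR call (0.0812). Without EC1118 in FSJ replicate 2 the sphingolipid (0.0561), hexose transport (0.339), beta-oxidation (0.0541) and stationary phase (0.0541) calls were lost. No beta-oxidation or stationary phase gene passed, also adjusted over the list alone (adjusted p = 0.248 and 0.425 with an estimated correlation). With arrays centred on their medians 31 genes were higher and 88 lower. Fitted on the 6 EC1118 arrays alone, 36 genes passed.

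The strains' lipid effects were set against each other gene by gene. Across all 5360 genes, which are not independent replicates, Pearson's r was 0.396 and Spearman's rho 0.312. Of the genes called in M25, 13 that rose and 55 that fell were also called in EC1118 in the same direction, where independent lists of these sizes would share 1.26 and 4.65, and 0 were called in opposite directions. Of the 161 genes that rose in M25, 144 had a positive fold change in EC1118, and of the 351 that fell, 275 had a negative one. The strains share no arrays, so no control was common to these comparisons. Both were fitted with the same variance estimate per gene, however, which can raise the number of shared calls above that of independent lists.

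**Figure D3:**
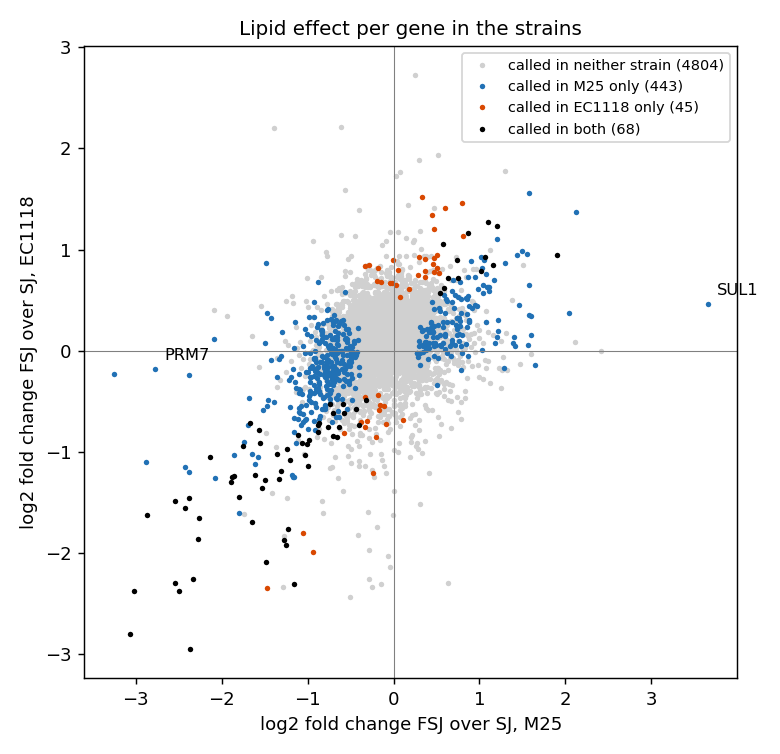
Log2 fold change of FSJ over SJ in EC1118 (vertical axis) against that in M25 (horizontal axis) for each of 5360 genes, coloured by the strain in which limma called the gene. The 68 genes called in both strains lie at the same sign in both, and SUL1 and PRM7 lie far from 0 in M25 and near it in EC1118.

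The interaction tested whether the lipid effect itself differed between the strains, and 10 genes passed. In SUL1 the effect was 3.19 lower on the log2 scale in EC1118 than in M25 (interaction -3.19, SE 0.24, adjusted p = 0.000173). PRM7, a pheromone-regulated gene, fell from 397 ± 49.3 to 59.0 ± 14.3 in M25 and measured 2716 ± 447 and 2375 ± 250 in EC1118 (SD, n = 3). Its interaction was 2.59 (SE 0.27, adjusted p = 0.00216). The effect was also lower in EC1118 for the vacuolar transporter VBA2 (-1.51, adjusted p = 0.0145), which is listed next to SUL1 on the chromosome, for the anaphase activator CDC20 (-1.46, adjusted p = 0.0441) and for YCT1 (-1.67, adjusted p = 0.0486). It was higher in EC1118 for PEX19 (1.84), the vacuolar channel YVC1 (2.36), the mitochondrial metal transporter MMT1 (1.32), YLF2 (2.14) and RIT1 (1.08), each at adjusted p = 0.0441. PEX19 was over the background on 2 of the 3 arrays of M25 in FSJ. YLF2 was over it on 2 of the 3 arrays of M25 in SJ and on none in FSJ, and with signals raised to the background its interaction was -0.045 (adjusted p = 0.93). PRM7 and VBA2 passed under each other scaling, offset, filter and variance model, and SUL1 also did except under the stricter filter, which left it out. The other 7 each lost the call under at least 1 of these, with adjusted p of up to 0.0553 for CDC20, 0.0737 for YCT1, 0.0915 for MMT1 and YVC1, 0.102 for PEX19 and 0.157 for RIT1. Under quantile normalization PEX19, YVC1, MMT1, YLF2 and RIT1 did not pass. SUL1 and PRM7 passed with every array left out in turn. VBA2 passed in 8 of the 12 such fits, PEX19 and MMT1 in 2, YVC1 and YLF2 in 1, and CDC20, YCT1 and RIT1 in 0, where the highest adjusted p was 0.136, 0.172 and 0.172. The count was 11 without EC1118 in FSJ replicate 1 and 2 to 6 without any other array. The median of all genes for this contrast was 0.20 on the log2 scale as deposited, 0.056 with quantile normalization and -0.049 with centring, under which the split of 6 higher and 4 lower in EC1118 became 1 and 4 (5 genes) and 4 and 35 (39 genes).

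Camera called 7 lists lower in EC1118 than in M25 relative to other genes, the median interaction of all genes being 0.20 on the log2 scale. Fry, which tests each list against no change and was added after the data were examined, called 0 (8 at an unadjusted p under 0.05). The sulfur list had a median interaction of -0.49 (2 of 28 members lower, SUL1 and YCT1, and 7 lower and 1 higher adjusted over the list alone). Its camera adjusted p was 4.62e-17 (adjusted p = 0.182 with an estimated correlation). In the other 6 lists no member passed over all genes, and adjusted over the list alone 1 was lower in glycolysis and in DAN/TIR and none in the rest. The amino acid median was -0.23 (7.63e-12; adjusted p = 0.215 with an estimated correlation). The cytosolic ribosomal proteins had -0.23 (4.62e-17; adjusted p = 0.158 with an estimated correlation) and glycolysis -0.22 (9.94e-08; adjusted p = 0.158 with an estimated correlation). The DAN/TIR (-0.31; 0.0022), cell wall (-0.080; 0.00582) and ergosterol lists (0.0103) had adjusted p = 0.489, 0.244 and 0.638 with an estimated correlation. The ergosterol list had 12 members above 0 and 12 below, and its median of 0.0018 and its test, downward, differ in sign. After quantile normalization the sulfur (1.3e-10) and amino acid lists (0.00139) alone of these 7 were called, and the glycolysis (0.0022) and cell wall (0.029) medians turned in sign. The ergosterol call was lost without M25 in FSJ replicate 1 (0.0803). Without EC1118 in SJ replicate 2 or EC1118 in FSJ replicate 3, 16 lists were called.

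The strains were also compared within each medium. HPF1, a cell wall mannoprotein known to reduce wine haze, measured 3902 ± 408 in EC1118 and 39.8 ± 3.16 in M25 in SJ (SD, n = 3; log2 difference 6.61, adjusted p = 2.53e-11) and stood at 6.47 in FSJ (adjusted p = 3.29e-11). PHO5, the repressible acid phosphatase, was 202-fold higher in EC1118 in SJ and 71.0-fold higher in FSJ. Higher in EC1118, with M25 under the background, were PHR1 (at least 5.78-fold in SJ and 5.23-fold in FSJ), CSS3 (at least 9.27-fold and 16.7-fold), YDR034C-A (at least 27.9-fold and 29.1-fold) and YBL005W-B (at least 29-fold and 15.4-fold). So were YHR214C-B (at least 21.6-fold and 20.7-fold) and, in FSJ, BSC1 (at least 27.8-fold; 3.46 on the log2 scale in SJ). M25 was higher for SUL1 (28.7-fold in FSJ, with EC1118 over the background on 2 of 3 arrays), MMT1 (13.2-fold and 5.27-fold), the tRNA gene YNCM0020W (11.3-fold and 6.45-fold), and the serine deaminase CHA1 (at least 6.7-fold and 13.2-fold). It was also higher for ZNF1 (at least 4.48-fold and 1.91-fold), the tRNA gene YNCD0013C (at least 2.05-fold and 2.06-fold), AQY3 (at least 4.79-fold in FSJ) and YSF3 (at least 1.19-fold in SJ). In SJ the EC1118 means lay under the mean background for SUL1 (17.1, against 53.6 ± 3.47 in M25; 1 of 3 arrays over it) and AQY3 (16.8, against 143 ± 12.6 in M25), so no fold is given. The background was exceeded on 2 of 3 arrays by PHO5 and YSF3 in M25 in SJ, by YNCD0013C in M25 in FSJ and by AQY3 and YNCM0020W in EC1118 in SJ. Sequence differences between each strain and the probes enter these values.

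The lists were tested between strains after the data were examined. Of 67 mitochondrial ribosomal protein genes, 41 were higher in EC1118 in SJ (48 adjusted over the list alone; median 0.66; camera adjusted p = 6.65e-21, and adjusted p = 0.0483 with an estimated correlation). In FSJ it was 55 (56 adjusted over the list alone; 2.74e-13, and adjusted p = 0.181 with an estimated correlation). In FSJ the sulfur genes were higher in M25 (19 of 28, with 1 higher in EC1118, or 20 and 3 adjusted over the list alone; adjusted p = 5.51e-11, and adjusted p = 0.366 with an estimated correlation). Higher in M25 too were 27 of 63 amino acid genes (6 higher in EC1118, or 28 and 6 adjusted over the list alone; 5.84e-07, and adjusted p = 0.461 with an estimated correlation). So were 12 of 24 replication genes (2 higher in EC1118, the same counts adjusted over the list alone; 0.000275, and adjusted p = 0.461 with an estimated correlation). The cytosolic ribosomal proteins were lower in EC1118 as deposited (25 of 81 higher in M25, 21 adjusted over the list alone; 6e-09, and adjusted p = 0.366 with an estimated correlation). So were cell wall genes (11 of 34 higher in M25 and 3 in EC1118, also adjusted over the list alone; 0.000318, and adjusted p = 0.252 with an estimated correlation), and both calls were lost with quantile normalization (0.0764). In SJ, 8 of 14 thiamine and pyridoxine genes were higher in EC1118 (8 adjusted over the list alone; 4.89e-05, and adjusted p = 0.677 with an estimated correlation). Of 28 sulfur genes 11 were higher in M25 and 1 in EC1118 (13 and 2 adjusted over the list alone; 0.0224, and adjusted p = 0.799 with an estimated correlation), a call lost without EC1118 in SJ replicate 2 (0.0771). Also higher in EC1118 in SJ were the stationary phase (9 of 29), oxidative stress (6 of 29), glycolysis (8 of 24), beta-oxidation (5 of 23) and trehalose lists (5 of 20, with 1 higher in M25). Adjusted over the list alone 9, 6, 14, 6 and 5 of their members were higher in EC1118 and 1, 0, 1, 1 and 1 in M25. Their adjusted p was 0.000839, 0.000851, 0.000851, 0.0245 and 0.0324, and adjusted p = 0.577 to 0.799 with an estimated correlation. The beta-oxidation call was lost without M25 in SJ replicate 3 (0.0625) or EC1118 in SJ replicate 1 (0.14), and the trehalose call without M25 in SJ replicate 1 (0.0846) or EC1118 in SJ replicate 1 (0.15). The replication (7 of 24, 12 adjusted over the list alone; 0.00156) and PAU genes (6 of 10, or 8 with 1 higher in EC1118 adjusted over the list alone; 0.0103) were higher in M25 in SJ, each with adjusted p = 0.677 with an estimated correlation. In all 10 lists were called in SJ and 6 in FSJ. In SJ limma called 972 genes, 485 higher in EC1118 and 487 higher in M25, and in FSJ 1866, 1309 and 557. For FSJ the median difference of all genes was 0.17 on the log2 scale as deposited, 0.035 with quantile normalization and -0.071 with centring. The split became 893 and 730 with quantile normalization and 704 and 1078 with centring. Fitted on the 6 FSJ arrays alone, 1233 genes passed.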

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

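Both tests of scaling, the test of brightness for the glycolysis, DAN/TIR, cell wall and ergosterol lists and the separation of the regroupings by kind were chosen only after the result was seen. For 10 genes the lipid effect differed between the strains in the limma interaction (EC1118 minus M25, log2). The difference was -3.19 for SUL1, -1.67 for YCT1, -1.51 for VBA2 and -1.46 for CDC20, where M25 rose more with lipids. It was 2.59 for PRM7, 2.36 for YVC1, 2.14 for YLF2, 1.84 for PEX19, 1.32 for MMT1 and 1.08 for RIT1. YLF2 was under the background in M25 in FSJ, where its fall was at least 1.07-fold, and with signals raised to the background its difference was -0.045 (adjusted p = 0.93). The EC1118 signals of SUL1 lay near the background in both media, so the size of the SUL1 difference is uncertain.

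In the same contrast camera called 7 lists, with camera adjusted p of 4.62e-17 for the cytosolic ribosomal proteins and the same for sulfur assimilation, 7.63e-12 for amino acid biosynthesis, 9.94e-08 for glycolysis, 0.0022 for DAN/TIR, 0.00582 for cell wall proteins and 0.0103 for ergosterol biosynthesis. No list was called with an estimated correlation (lowest adjusted p = 0.158). For the sulfur and amino acid lists, scaling between arrays is argued against by an adjusted p of at most 0.00139 under either other scaling, and brightness of the members by medians lower than all of 10000 random lists matched on mean signal (percentile 0). For the other 5 lists scaling may account for the calls, since after quantile normalization the lowest adjusted p was 0.184. Brightness may also account for glycolysis, DAN/TIR, cell wall and ergosterol (lowest percentile 7.21), but the ribosomal protein median of -0.23 lay at percentile 0.32 of its matched lists (middle 95% from -0.20 to -0.065). Matched lists were drawn gene by gene, so no percentile here allows for correlated members. Brightness is therefore not decided for the ribosomal proteins. A difference between the strains in sulfur and amino acid genes stays open as a hypothesis, as does a correlation of their members.

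The arrays were also regrouped. For the averaged lipid effect, 100 of the 200 regroupings within strains were drawn, and the real one alone gave as many as 560 genes (1 of 100, highest other 297). This makes chance unlikely for that count but does not exclude it, since 1 of 100 is the smallest share such a draw can give. For the correlation of the strains' effects 2 of 100 were as large (0.396, highest other 0.424), a share under the 5% limit. Among the 85 drawn that kept the real media groups of neither strain, 0 were as large, but the highest was 0.368. Chance is thus made unlikely for the correlation, but it is not excluded. Chance stays open for the lists of the averaged effect (5 of 100 gave as many as 18, highest other 21) and the lists of the interaction (65 of 100 gave as many as 7, highest other 21). These regroupings were drawn again after their listing order was changed, and the first draw had put the lists of the averaged effect under the 5% limit. For the interaction 5 of 100 gave as many as 10 genes (highest other 248). The 4 others kept the real media groups of 1 strain, which carries its lipid effect into the contrast, and among the 85 drawn that did not the highest count was 0. Chance therefore stays undecided for the interaction. Among those 85, 2 gave as many lists for the averaged effect and 50 for the interaction. Within a strain or medium the 10 splits are too few for a share under 0.05: the real split alone was as large, 1 of 10, with 512 genes in M25 (highest other 0), 113 in EC1118 (1), 972 between strains in SJ (0) and 1866 in FSJ (0).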

How the results depend on the processing

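The fry test, the tests of lists between strains and their alternatives were added only after the data were examined. The counts of genes for the averaged effect, for each strain and between strains stayed within 1.5 times under every other scaling, offset and filter. The genes behind similar counts differed. Of the 512 genes called in M25, 299 were also called with quantile normalization (342 in all) and 352 with centring (656 in all). Of the 1866 between strains in FSJ these were 1349 and 1261, and of the 560 for the averaged effect 471 and 498. The interaction count of 10 moved to 5 with quantile normalization, 39 with centring, 6 with log2(signal + 16) and 2 with the stricter filter. With only the groups compared, the count fell to 36 in EC1118 and 1233 between strains in FSJ and rose to 567 in M25 and 1237 between strains in SJ. With an estimated correlation 0 lists were called for the averaged effect (8 at an unadjusted p under 0.05), against 18 with camera's preset. Fry, which tests against no change and not against other genes, called 17 there. For the interaction 0 were called with an estimated correlation (5 unadjusted), against 7 with the preset, and quantile normalization gave 3 and fry 0 (8 at an unadjusted p under 0.05). Between strains an estimated correlation left 1 of 10 lists in SJ, where fry called 11, and 0 of 6 in FSJ (4 unadjusted), where fry called 18. The correlation of the strains' effects was 0.443 with log2(signal + 16), 0.459 with the stricter filter and 0.312 by Spearman, and neither centring nor the block can move it. The cause of these moves was not tested. Over genes called in at least 1 strain the correlation was 0.710, but these genes were chosen by the same effects, which favours a larger value.

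With 1 array left out, counts ranged from 353 to 771 for the averaged effect, 242 to 659 in M25, 76 to 146 in EC1118, 2 to 11 in the interaction, 660 to 1125 in SJ and 1463 to 1829 in FSJ. Lists ranged from 16 to 18 (averaged) and 7 to 16 (interaction), and the correlation from 0.309 to 0.467. Without EC1118 in FSJ replicate 2 the averaged count was 411, and without replicate 3 the averaged, M25 and EC1118 counts were at their highest (771, 659 and 146). Of 114 named genes called for the averaged effect, 30 lost the call under at least 1 alternative and 0 reversed.

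Same-numbered arrays are linked in the labels by the number alone. Of 18 such pairs, 3 had a correlation of deviations over 0.1 (-0.174 to 0.233), and 5 of 12 arrays correlated best with their own number. With 3 arrays per group these values cannot exclude that same-numbered arrays shared a run. With the replicate number as a block the counts were 481, 457 and 103 for the lipid effects, 2 for the interaction (SUL1 and PRM7), 895 and 1739 between strains, and 18 and 7 lists, with a correlation of 0.396. Signals near the background (16.6 to 21.7) limit folds to bounds.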

Other observations

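The tests of neighbour placing, of closeness to the background, of the iron regulon and of differences among the PAU genes were chosen only after the result was seen. Between the strains, 721 genes were called the same way in both media, 427 higher in EC1118 and 294 higher in M25, and 3 in opposite ways. Of 86 tRNA genes tested, limma called 30 higher in M25 and 0 higher in EC1118 in both media (37 and 0 at an unadjusted p under 0.05), and 56 were not called. Of 5212 protein-coding genes it was 259 and 427, and no enrichment of either kind of gene was tested. Among genes under the background on all arrays of 1 strain and above it on all arrays of the other, 13 were under it in M25 and 7 in EC1118. The former included the Ty genes YBL005W-B (8.47 against 472 in EC1118), YHR214C-B (9.73 against 425) and YMR045C (9.58 against 279), and the latter CHA1 (200 in M25 against 9.73) and the small nucleolar RNA gene SNR31 (46.2 against 9.38). These genes were chosen by that state after the values were seen.

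Neighbouring genes shared this state in 2 adjacent pairs, YJL218W with REE1 and YOR385W with PHR1, all at background in M25. Chance placing is argued against, since 10000 random placings among 5637 genes gave a mean of 0.0329 pairs and at most 2 (one-sided permutation p = 5e-04). The median signal in EC1118 was 5.62 times the background, with 4.25 for YJL218W and 11.8 for REE1 as the extremes of the 4 genes. They were chosen as above the background in EC1118, which raises this value, so it argues only weakly against closeness to the background. Counted over the measured genes alone, the definition tried first, there were 3 pairs (one-sided permutation p = 1e-04, the smallest 10000 placings can give), the added one being the iron uptake genes FRE3 (YOR381W; 1.18 in M25 against 35.9 in EC1118) and FIT2 (YOR382W; 5.47 against 115), and FDH1 (YOR388C; 10.9 against 27.5) of the same stretch was at background in M25 too. An iron response cannot be told apart, with a median strain difference, averaged over the media, of 0.078 on the log2 scale over 28 iron regulon members, FRE3 and FIT2 among them and 17 higher in EC1118. The list median was -0.13 in SJ and 0.38 in FSJ. Sequence absent or altered in M25 may be the source, but the arrays cannot tell, since the choice of genes fixes the test (0 arrays over background).

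The PAU genes fell with lipids while the DAN/TIR list was not called. The effects of the 10 PAU probe sets differed from each other (from -2.70 for PAU17 to -0.66 for PAU4). A one-sided exact permutation test gave p = 0.005, the smallest that 400 arrangements of the media within strains can give. The probe sets therefore did not share 1 common fold. Probe sets can also give unlike folds for the same transcript, so the test cannot decide whether all 10 read a single one. Mixed cross-hybridisation stays open too. Whether signals near saturation hide a DAN/TIR change stays open. The spread of the averaged effect over the 95 genes at a mean log2 signal in SJ of 12 or more was 0.443 times that over the 534 genes from 10 to 12. Bright genes that respond little would give such a ratio too, so it cannot decide. PAU17 lies among those 95 and fell by 2.70, so a large fall was measurable there. Of the 37 genes at or above the SJ signal of DAN1 (12.45), which include DAN1 itself, 0 were called lower and 1 higher. A regulatory difference between the families was not tested.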
